A study of Mus musculus with 2 samples.

How the data were processed

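Accessible chromatin was measured by DNase-seq, in which DNase I cuts nuclear DNA where it is not packed by nucleosomes and the cut ends are sequenced. The 2 libraries came from kidney tissue of adult female mice aged 18 to 20 months. The strain, B6CASTF1/J, is the first-generation hybrid of C57BL/6J and CAST/EiJ. Per the labels, the libraries are biological replicates 1 and 2 of 1 group and come from separate biosamples that share a donor identifier. It is therefore open whether they came from separate animals, and the spread between them may be partly technical. With 1 group there was no contrast between conditions, so each library was analysed by itself and the libraries were then compared.

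The authors deposited for each library a pair of peak lists, a list of footprints and a table of false discovery rates of the local cut rate, all on mm10 (GRCm38). Per the deposited description of each sample, all were derived from the filtered alignments of that library alone, so no peak was called on pooled libraries. The aligner, the peak and footprint callers, their versions and their thresholds are not given in the sources used here. The signal of a peak is the height deposited by the authors, in their own scaling. In each library 100% of low heights were whole multiples of a fixed step within a tolerance of 0.1 step, 0.00500 in replicate 1 and 0.00560 in replicate 2. The median peak stood 122 and 133 such steps high. What a step stands for is not given in the sources used here, so the depth of the libraries is unknown. The p-value, q-value and summit columns of the deposited peak lists each held a single repeated number and were not used, so peak midpoints stood in for summits. The footprint table held an FDR of 0.01 in every line. The cut rate table of the authors gives an adjusted p-value, the FDR, for runs of bases below 0.05.

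By a rule fixed in advance for lists nested in one another, the longer peak list of each library was the main list. Of the shorter list, 97.7% and 98.5% of regions lay wholly inside regions of the longer list in replicates 1 and 2. Counts covered chromosomes 1 to 19 and X, and chromosome Y was counted apart. Peaks were shared if they overlapped a peak of the other library by at least 1 bp, and footprints if a footprint of the other library covered at least 50% of them. Chance levels came from 100 random placements of the intervals within their chromosomes, outside assembly gaps, or within the peaks of the library for footprint sharing. Genomic locations used 20 such placements. Heights were compared across peaks matched 1 to 1, and peaks are not independent replicates.

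Sequence was GRCm38.p6 and gene models were GENCODE M21, comprehensive set. A promoter peak overlapped the 1 kb on either side of an annotated transcription start site (TSS). The promoter height of a gene is the height of its highest promoter peak, or 0 where no peak was called. Distal peaks lay over 1 kb from every TSS. The 26 gene lists and the 28 sequence motifs were fixed before the data were examined (the erythroid gene Ahsp matched no gene model and was left out), as were the main settings and most of the alternatives. For each list the share of members with a promoter peak was compared with that of the other protein-coding genes, among 21755 in all, by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 26 lists. A list was called higher or lower if the adjusted p was under 0.05 with the same direction in both libraries. Genes are not independent replicates, so these p-values describe these libraries only. The median number of distal peaks within 50 kb of a member TSS was ranked among 10000 random lists of equal size, matched on deciles of gene length, and called beyond the 97.5th or 2.5th percentile in both libraries.

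Motif matches on either strand were counted per Mb in footprints padded by 5 bp and in the rest of the same peaks, and in windows of 200 bp at distal peak centres and windows 2 kb away that overlapped no peak. Ratios carry exact binomial 95% intervals, which cover counting error only, and a motif was called if both intervals excluded 1. Each motif was also shuffled 5 times. A gene was assigned a CpG island if the ratio of observed to expected CpG was at least 0.6 and GC content at least 50% in the 1 kb around its outermost annotated start. Its other TSSs were not classed, although promoter peaks were counted at all of them. Intervals of shares are exact (Clopper-Pearson) 95% intervals.

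The genes named below follow a rule fixed before the data were examined. For each list they are up to 3 members with a promoter peak in both libraries and the highest mean promoter height, up to 2 members without a promoter peak in either library (in alphabetical order), and members whose call differed between the libraries where there were at most 3. Over all genes they are the 5 with the highest promoter heights, the 5 with the most distal peaks by the lower count of the libraries, and the gene nearest each of the 3 highest peaks of a library without a counterpart in the other. Some genes that this rule names are not reported here.

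The alternatives were the shorter peak list, stricter height thresholds, other overlaps, promoter windows of 500 bp and 2 kb, distances of 20 and 100 kb, a background without receptor families and predicted genes, other paddings and motif windows, and each library alone. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9. The procedures were tested on simulated data. Of 5000 simulated peaks, 60.0% were made shared and 60.0% were found. Of 20 simulated lists of 25 genes, 16 were called at a share of 95% against 70%, and 12 at 35% against 70%, while 0 of 60 unchanged lists were called among 21755 genes. Distal lists raised by 3 peaks per gene were called in 20 of 20 cases and unchanged lists in 0 of 60. These simulated counts were independent between genes, came from a single library and were tested on the high side only, against fewer random lists. They therefore do not give the error rate of the real distal calls. Of 2015 planted motif sites expected in footprints, 2009 were found. Alleles of the parental strains were not analysed here, and CAST/EiJ differs from the reference at many positions, which can affect alignment and motif matches.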

Results

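Kidney chromatin of aged female B6CASTF1/J mice was open at 145393 sites in replicate 1 and 132670 in replicate 2, 139032 ± 8997 (SD, n = 2) per library. The peaks covered 33.1 and 25.8 Mb, 1.26% and 0.981% of the genome. The median peak was 200 bp wide in replicate 1 and 192 bp in replicate 2. Median heights were 0.610 and 0.745 in the scaling of the authors, and the highest peaks reached 103.9 and 66.9. All values below are from these 2 libraries, which form 1 group, so they describe the open chromatin of this tissue and how well it repeated between libraries.

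The highest promoter peak of all protein-coding genes lay at the predicted gene Gm21887 on chromosome X, at 60.9 and 65.3 in replicates 1 and 2. Dynlt1b, which encodes a dynein light chain, followed at 44.4 and 52.8. Ing2, a chromatin-binding growth regulator, stood at 23.5 and 35.4, Bahcc1 at 20.8 and 36.9, and the aspartyl aminopeptidase gene Dnpep at 22.9 and 34.4. In the Gm21887 promoter peak of replicate 1, X:170009861-170010160, 100% of the 24-base words occurred more than once in the assembly, and in that of Dynlt1b, 17:6429981-6430180, 70.6%. The corresponding share was 0 at Ing2, Bahcc1 and Dnpep. The count included chromosome Y, and all of the Gm21887 words also occurred on another chromosome, so a copy on Y alone could give its value. Distal peaks were counted within 50 kb of any annotated TSS of a gene, so genes with TSSs far apart were searched over more sequence. The most surrounded Tns1, which encodes the focal adhesion protein tensin 1, with 112 and 108. B4galt5 had 65 and 68, Nav2 71 and 62, Gse1 60 and 71, and Kalrn 74 and 60.

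Of the peaks of replicate 1, 71.9% overlapped a peak of replicate 2, against 2.26% after random placement. In the other direction 80.1% were shared, against 2.45%. Sharing rose with height, from 21.2% and 34.0% in the lowest decile of replicates 1 and 2 to 99.2% and 98.4% in the highest. Across 95524 matched peaks, heights had a Spearman rho of 0.947 and a Pearson r of 0.961 on the log10 scale. These are correlations across peaks, which are not independent replicates. The median log2 ratio of replicate 1 over replicate 2 was -0.16 with an SD of 0.41.

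**Figure D1:**
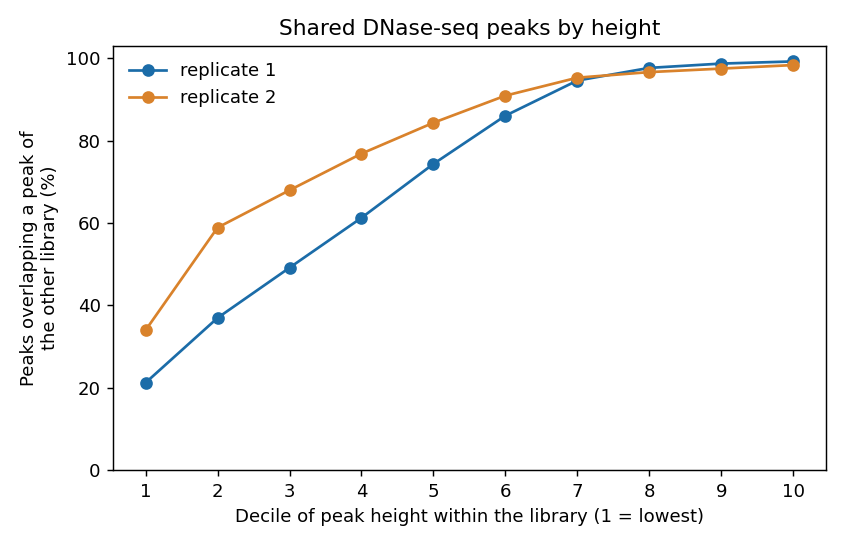
Percentage of peaks that overlapped a peak of the other library by at least 1 bp, by decile of peak height within each library (1 is the lowest decile). Points are the values of replicate 1 (blue) and replicate 2 (orange), which rise from 21.2% and 34.0% to 99.2% and 98.4%.

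Peaks with neither a peak nor a listed run of significant cutting in the other library numbered 35794 in replicate 1 (24.6%) and 18560 in replicate 2 (14.0%), with median heights of 0.3002 and 0.308. The highest of replicate 1, with a height of 2.10, lay at 15:85667561-85667620 in a noncoding exon, where Gm49539 and Lncppara overlap. Its nearest protein-coding gene was Ppara, a lipid-sensing nuclear receptor, 67392 bp away. Those next in height lay in an intron of Tsc22d1 (14:76473541-76473700, height 1.62) and in a coding exon of Hoxa9 (6:52224021-52224660, height 1.59). In replicate 2 the highest, with a height of 3.20, was intergenic at 11:90739641-90739760, nearest to Tom1l1. It was followed by sites in introns of Isoc2b (7:4857461-4857620, height 2.24) and Foxk1 (5:142451941-142452120, height 1.90), the latter nearest to the TSS of Ap5z1.

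For genomic locations each peak was classed by its midpoint rather than by overlap, as a promoter peak if the midpoint lay within 1 kb of a TSS. Promoters held 27.8% of peaks in replicate 1 and 29.4% in replicate 2, a mean of 28.6% ± 1.12 (SD, n = 2), against 6.36% and 6.38% of randomly placed intervals. Exons held 5.501% and 5.499%. Introns held 37.6% and 36.2%, and intergenic sequence 29.1% and 28.9%, against 49.98% and 49.93% at random. Promoter peaks were the highest, with medians of 1.20 and 1.45, and intergenic peaks the lowest, with 0.490 and 0.588. The promoter share moved to 21.2% with a window of 500 bp and to 36.8% with one of 2 kb.

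Most genes of the kidney tubule had a promoter peak. In the proximal tubule list, which holds the transporters and enzymes that reclaim filtered solutes, 27 of 30 members had a promoter peak in both libraries. The highest were Slc6a19, a neutral amino acid transporter (ENSMUSG00000021565.16, 13:73679745-73704865), at 5.21 and 8.48 in replicates 1 and 2, Lrp2, the endocytic receptor megalin (ENSMUSG00000027070.14, 2:69424340-69586065), at 4.70 and 5.76, and Pck1, a gluconeogenic enzyme, at 5.27 and 4.73. Kap and Slc22a30 had no promoter peak in either library. All 16 thick ascending limb genes had promoter peaks, among them Egf at 6.58 and 6.85 and Ptger3 at 1.46 and 2.75. All 12 principal cell genes did as well, among them the sodium channel subunits Scnn1g (5.67 and 6.21) and Scnn1a (2.25 and 3.73) and the transcription factor gene Gata3 (3.53 and 5.74). For the proximal tubule list the share of 90% (95% interval 73.5% to 97.9% in each library) stood against 71.3% and 70.6% of all protein-coding genes, and the adjusted p of Fisher's exact test was 0.0377 and 0.0279. The thick ascending limb list gave an exact test adjusted p of 0.0176 and 0.0117, and the principal cell list 0.0377 and 0.0361. All 3 calls ended with the shorter peak list, with the higher 50% of peaks and with a background without receptor families and predicted genes. The thick ascending limb call also ended with a promoter window of 500 bp, where 93.75% of members had a peak, and the principal cell call with one of 2 kb, where 100% did. The median height of members with a peak was 2.31 and 2.66 in the proximal tubule list, 1.42 and 1.73 in the thick ascending limb list and 1.74 and 1.92 in the principal cell list, below the 4.998 and 6.10 of all genes with a peak, and heights of lists were not tested.

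**Figure D2:**
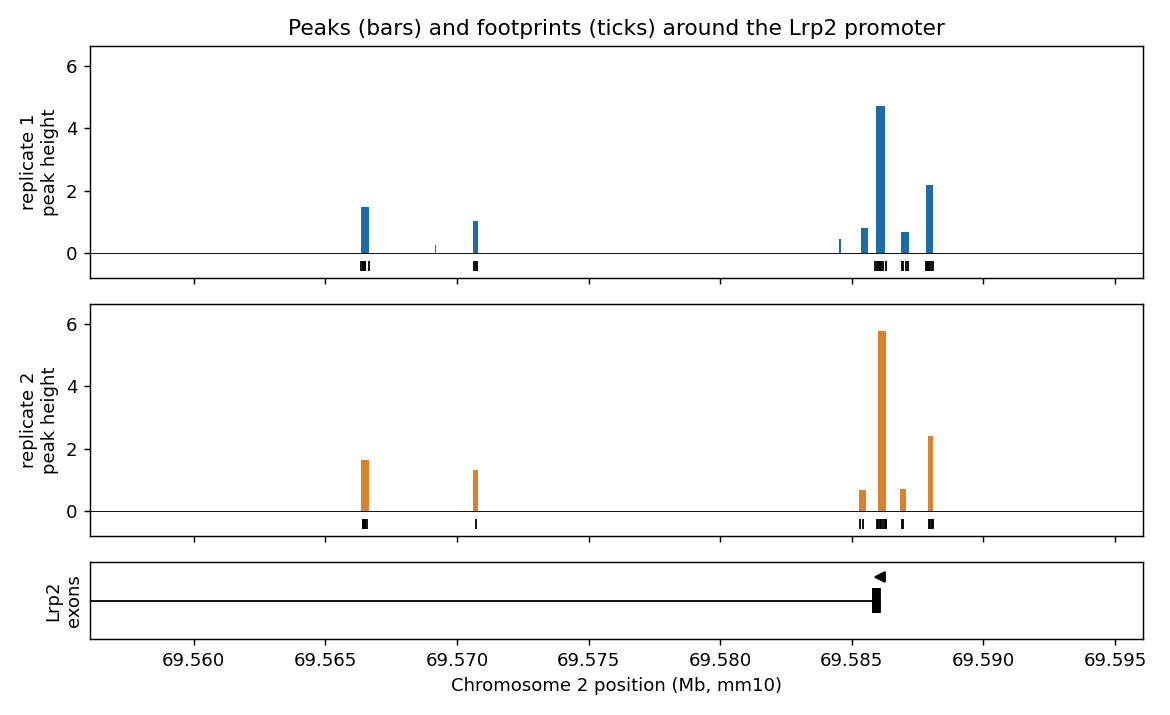
Peaks (bars, height in the scaling of the authors) and footprints (ticks) over 40 kb around the Lrp2 promoter on chromosome 2, in replicate 1 (blue) and replicate 2 (orange), with the Lrp2 exon and the direction of transcription at the bottom. The promoter peaks of 4.70 and 5.76 are the highest among 8 peaks in replicate 1 and 6 in replicate 2.

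Other nephron cell types did not pass the test in both libraries. The distal convoluted tubule list had 11 and 10 of 11 promoters open, with Emx1 at 4.13 and 5.79, the kinase gene Wnk4 at 3.37 and 5.85, and the thiazide-sensitive cotransporter gene Slc12a3 at 2.37 and 3.35. The calcium channel gene Trpv5 had a promoter peak in replicate 1 only, with a height of 0.3002. The intercalated cell list had 12 and 11 of 14, led by the ammonia transporter gene Rhbg (3.25 and 5.81), the proton pump subunit gene Atp6v0a4 (3.08 and 4.35) and Slc4a9 (2.04 and 2.04). Its members Aqp6 and Slc4a1 had none. Podocyte genes were open in 14 and 13 of 15 cases, with Cdkn1c at 3.78 and 6.55 and Synpo at 3.47 and 5.09. The slit diaphragm gene Nphs1 had a peak of 0.470 in replicate 1 only. The exact test gave an adjusted p of 0.0592 and 0.250 for the distal convoluted tubule, 0.424 and 0.801 for intercalated cells and 0.108 and 0.319 for podocytes.

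Endothelial promoters were open in 16 of 16 cases, with Ehd3 at 4.59 and 5.38, the adhesion gene Esam at 4.36 and 5.26, and Vwf, which encodes von Willebrand factor, at 3.59 and 2.95 (exact test, adjusted p = 0.0176 and 0.0117). This call ended under the same 3 alternatives as the tubule calls. Stromal genes were open in 12 and 11 of 15, including the collagen gene Col1a1 (7.25 and 6.15), the growth factor receptor gene Pdgfra (3.76 and 4.11) and Cspg4 (2.69 and 3.78), while Lum and Postn had no promoter peak. That list was not called, with an exact test adjusted p of 0.6001 in replicate 1 and 1 in replicate 2. Leukocyte promoters were mostly closed. The lymphocyte list had 4 and 3 of 16 open, with Lck, a T cell kinase, at 6.34 and 7.57 but the T cell surface protein genes Cd8a and Cd3d at 0.490 and 0.260 in replicate 1. The exact test adjusted p was 0.00218 and 3.5e-04. The macrophage list had 6 of 16 open in each library, led by the antigen presentation genes H2-Aa (3.85 and 4.38), H2-Ab1 (3.11 and 2.12) and Cd74 (1.02 and 1.24), with an exact test adjusted p of 0.0139 and 0.0198. Adgre1 and C1qa had none.

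Promoters of regulatory genes were open in most cases. All 26 transcription factor genes of the adult nephron were open, among them Esrra, an oestrogen-related receptor of mitochondrial genes, at 17.6 and 29.8, Ppara at 10.0 and 13.2, and the mineralocorticoid receptor gene Nr3c2 at 9.99 and 13.1 (exact test, adjusted p = 0.00227 and 0.00127). All 17 immediate early genes had promoter peaks, with Jun at 15.9 and 24.95, Jund at 13.8 and 18.9, and Atf3 at 11.6 and 21.1. All 17 circadian clock genes did too, led by the repressor gene Nr1d1 (16.4 and 24.2), Tef (13.2 and 23.9) and Per2 (14.3 and 21.4). For both of these lists the exact test adjusted p was 0.0139 and 0.0117. Of 39 Hox genes, which pattern the body axis, 35 and 36 were open, with Hoxa7 at 9.74 and 8.90 and a promoter peak of 6.13 and 9.25 counted for both Hoxc5 and Hoxc10 (exact test, adjusted p = 0.0176 and 0.00541). All 9 nephron progenitor genes were open, with Sall1 at 5.02 and 5.40, but the list missed the threshold with an exact test adjusted p of 0.0927 and 0.0958. The genes named here are the highest of their lists. The median height of members with a peak was 3.51 and 4.50 for the nephron transcription factors, 3.86 and 3.71 for Hox genes and 0.946 and 0.947 for nephron progenitor genes, each below that of all genes with a peak. It was 7.35 and 10.1 for immediate early genes and 10.6 and 16.2 for clock genes. The injury and senescence list was not called either, with 14 and 13 of 16 open and an exact test adjusted p of 0.211 and 0.501. The cell cycle inhibitor genes Cdkn1a (7.59 and 10.0) and Cdkn2b (6.07 and 6.73) were open, Lcn2 had no promoter peak, and the injury marker Havcr1 had a peak of 0.220 in replicate 1 only.

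The housekeeping control lay above all protein-coding genes, and the negative controls other than the neuronal one lay below. All 20 housekeeping promoters were open, with the ribosomal protein gene Rplp0 at 21.5 and 17.8 (exact test, adjusted p = 0.00817 and 0.00643). Olfactory receptor promoters were open in 24 of 1135 cases in each library. Striated muscle had 6 of 18 in each library, hepatocyte genes 8 and 6 of 19, and germ cell genes 6 and 7 of 17. The exact test adjusted p of these was 0.00605 and 0.00541, 0.0176 and 0.00327, and 0.00817 and 0.0254. Albumin, the main secretory product of hepatocytes, had no promoter peak at Alb. The germ cell gene Gdf9 stood at 17.2 and 25.1. Erythroid genes had 3 of 12 and adrenal cortex genes 3 of 9 in each library, with an exact test adjusted p of 0.00622 and 0.00541 for the former and 0.0353 and 0.0361 for the latter. With a window of 2 kb the muscle and adrenal cortex calls ended, at 55.6% and 38.9% of members against 73.2% of all genes, and the adrenal cortex call also ended with the shorter peak list, at 33.3% against 67% of all genes. Neuronal genes, chosen as a negative control, were open in 14 of 18 cases in each library, a share of 77.8% that lay above that of all protein-coding genes. These neuronal genes, adipocyte genes (8 of 13) and urothelial genes (4 of 9) were not called, with an exact test adjusted p from 0.163 to 0.795. With a window of 500 bp the urothelial list was called lower, at 27.8%. In all, 9 lists were called higher, 8 lower and 9 neither.

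**Figure D3:**
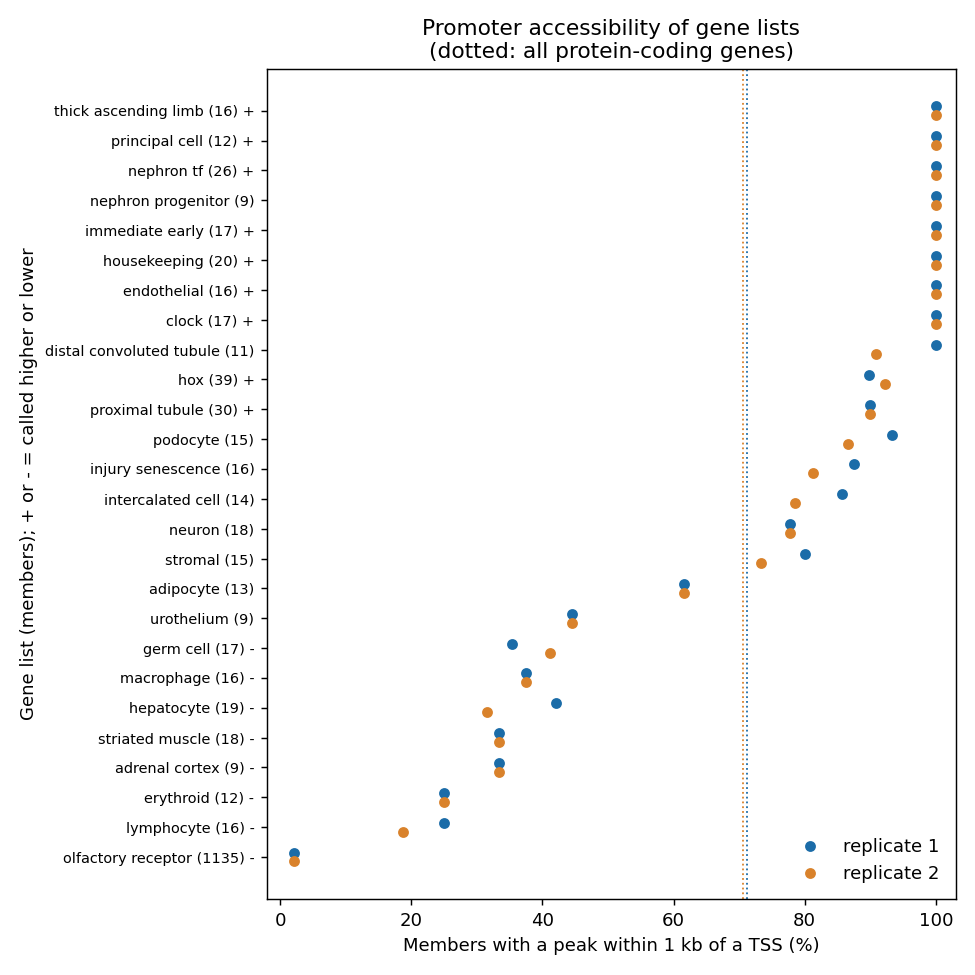
Share of members of each gene list with a peak within 1 kb of a TSS in replicate 1 (blue) and replicate 2 (orange), with the number of members in parentheses. Plus and minus signs mark the 9 lists called higher and the 8 called lower, and dotted lines mark all protein-coding genes at 71.3% and 70.6%.

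Promoter type and background were varied for these calls. Of 9741 genes with a CpG island at their outermost start, 97.9% and 97.7% had a promoter peak at any TSS. Of 12014 genes without an island there, 49.7% and 48.5% did. Genes of the latter class may have an island at another TSS. Among genes without an island at their outermost start, chosen as a subset after seeing the data, the proximal tubule, thick ascending limb, principal cell, endothelial, nephron transcription factor and Hox lists were called higher, and of the lists called lower only the olfactory receptors were. The shares of the other 7 all stayed below that background in both libraries, between 18.2% (11 germ cell genes left) and 42.1% (19 hepatocyte genes in replicate 1), without passing the test at these numbers. The immediate early, clock and housekeeping lists kept 3, 4 and 5 members there, all of them open, and were not called. The neuronal negative control kept 12 members there and was not called, but its shares of 83.3% and 75% also lay above that background. Its exact test adjusted p was 0.0469 and 0.137, so higher shares in this subset were not limited to kidney lists. With receptor families and predicted genes left out of the background, which left 18366 genes, the nephron transcription factors were the 1 list called higher, and the calls of the proximal tubule, thick ascending limb, principal cell, endothelial, immediate early, clock, housekeeping and Hox lists ended. Their shares were unchanged, at 90% for the proximal tubule, 91.0% for Hox genes as the mean of the libraries and 100% for the others, while the background rose from 70.9% to 80.3%. With the shorter peak list, and with the higher 50% of peaks, 5 lists were called higher, without the proximal tubule, thick ascending limb, principal cell and endothelial lists. The shares of these 4 were still 81.7%, 93.75%, 91.7% and 96.9% against 67% of all genes with the shorter list, and 85%, 87.5%, 87.5% and 90.6% against 63.9% with the higher 50%.

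Distal peaks clustered around 7 lists in both libraries, against a median of 6 and 5 distal peaks per gene in replicates 1 and 2. Proximal tubule genes had a median of 11.5 and 9.5 distal peaks within 50 kb, and Pck1 alone had 46 and 32. Nephron transcription factors had 13.5 and 13, with 29 and 42 around Ppara. Immediate early genes had 14 in each library and clock genes 13 and 12, with 42 in each around Nr1d1. Endothelial genes had 11.5 and 12.5, and injury and senescence genes 10.5 and 9. The Hox genes, whose members lie in clusters and share peaks, had 32 and 21. Olfactory receptors had a median of 0 in each library, below every random list. Thick ascending limb genes had 10.5 in replicate 1, at the 97.9th percentile of random lists, but 5.5 in replicate 2, at the 51.0th. With a distance of 100 kb the proximal tubule call ended, at a lowest percentile of 95.8. With the higher 50% of peaks the housekeeping list was also called, at percentiles of 98.1 and above. Random lists were drawn from all protein-coding genes, olfactory receptors included, and the reduced background was not applied here.

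Footprints, short protected stretches within open chromatin that mark bound proteins, numbered 472224 in replicate 1 and 385715 in replicate 2, 428970 ± 61171 (SD, n = 2). Their median width was 10 and 11 bp. Of them, 79.6% and 83.5% lay in peaks, against 1.46% and 1.16% at random. Of the footprints of replicate 1, 43.1% were covered by a footprint of replicate 2, against 13.4% of footprints placed at random within peaks, and 52.8% against 16.7% in the other direction. Cutting below an FDR of 0.001 extended over 37.9 and 29.3 Mb, and below 0.05 over 58.7 and 44.7 Mb, of which 39.9 Mb were shared.

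The motif of CTCF, the insulator protein, was 39.4-fold (95% interval 35.8 to 43.6) denser in footprints than in the rest of the peaks in replicate 1 and 30.2-fold (27.4 to 33.3) in replicate 2. NRF1, an activator of mitochondrial genes, reached 53.8-fold and 45.3-fold, REST, the repressor of neuronal genes, 27.8-fold and 12.7-fold, and NFI 9.80-fold and 12.5-fold. SP and KLF factors reached 11.2-fold and 10.1-fold and the E-box of BMAL1, CLOCK and USF factors 7.45-fold and 8.50-fold. Of factors of the tubule, HNF1 stood at 3.66-fold and 3.27-fold and HNF4 at 1.90-fold and 2.04-fold. In all, 15 motifs were called higher, 7 lower and 6 neither. The motifs called lower included AP-1 at 0.859-fold and 0.871-fold, GATA at 0.474-fold and 0.467-fold and FOX at 0.495-fold and 0.489-fold. Every shuffled version of the AP-1, FOX and GATA motifs also lay below 1 in both libraries. AP-1 itself lay above all of its shuffled versions, which reached at most 0.729 and 0.727, so it was not depleted relative to them. When calls had to lie beyond every shuffled version, a criterion added after seeing the data, only GATA was called lower. Under the same criterion 11 motifs were called higher, without REST, the nuclear receptor direct repeat, the NRF2 and MAF element and TFCP2L1. Shuffled versions of the REST motif had too few matches for a comparison. The nuclear receptor direct repeat missed the criterion in replicate 1 only, where the ratio of a shuffled version was infinite. That version had no match in the rest of the peaks, so its ratio does not show that shuffled sequence reached the motif. In replicate 2 the shuffled versions of this motif reached at most 0, against 4.31 for the motif itself.

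Sites with a footprint in both libraries lay at many of the named promoters, and the examples here were chosen after the sites were seen. The Lrp2 promoter held the HNF4 site TGCACTTTG at 2:69586175-69586183, intergenic and 114 bp upstream of a TSS. At Tef the E-box CACGTGAC lay in the untranslated region at 15:81811054-81811061, 12 bp downstream of a TSS. The antigen presentation genes H2-Aa, H2-Ab1 and Cd74 each held a box for NF-Y, a regulator of their class, at 17:34287867-34287873 and 18:60803644-60803650 (both intergenic, at H2-Aa and Cd74) and 17:34257767-34257773 (noncoding exon, at H2-Ab1). Snap25, a neuronal gene, held the REST sites TCAGCACCCTGGACAG (2:136714289-136714304) and TCAGCACCGCGGACAG (2:136714339-136714354) in an intron. Atp6v0a4 held the TFCP2L1-type site CCAGCCAAAACCAG at 6:38124763-38124776, in an untranslated region 184 bp upstream of a TSS. Such sites were not limited to genes of a matching cell type. NF-Y boxes also lay at Rbfox3, Emx1, Jund and Ywhaz, the same E-box at Gata3, Zpbp and Hoxa7, a TFCP2L1-type site at Cd8a, a PU.1 site at Synpo, a myogenic E-box at Plin1 and a CRX site at Gdf9.

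At distal peaks, 103050 in replicate 1 and 92256 in replicate 2, the CTCF motif was again enriched. It was found in 5.14% and 5.59% of windows, against 0.0683% and 0.0743% of windows 2 kb away, a ratio of 75.2 in each library. REST sites were 130-fold and 245-fold more frequent, on 2 background matches in replicate 1 and 1 in replicate 2, and the interval in replicate 1 ran from 35.3 to 1083. NFI stood at 25.6-fold and 37.1-fold, HNF1 at 4.68-fold and 7.97-fold, HNF4 at 2.33-fold and 2.83-fold, and AP-1 at 1.43-fold and 1.54-fold. In all, 21 motifs were called higher, 2 lower (GATA and CRX) and 5 neither. Beyond every shuffled version, 14 were called higher and 0 lower, and the calls of ESRR, the NRF2 and MAF element, TFCP2L1, NRF1, PAX8, REST and the myogenic E-box ended. The NRF1 call ended through replicate 1 alone and the REST call through replicate 2 alone. In each case a shuffled version had no match in the windows 2 kb away and so an infinite ratio. In replicate 2 NRF1 stood at 6.57-fold, above its shuffled versions, which reached at most 4.63. The myogenic E-box, a negative control, was among those called higher, at a mean of 2.51-fold. Neither direction was stable for ESRR, at 0.966-fold in the higher 50% of peaks, or for FOX, at 0.987-fold in windows of 100 bp.

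**Figure D4:**
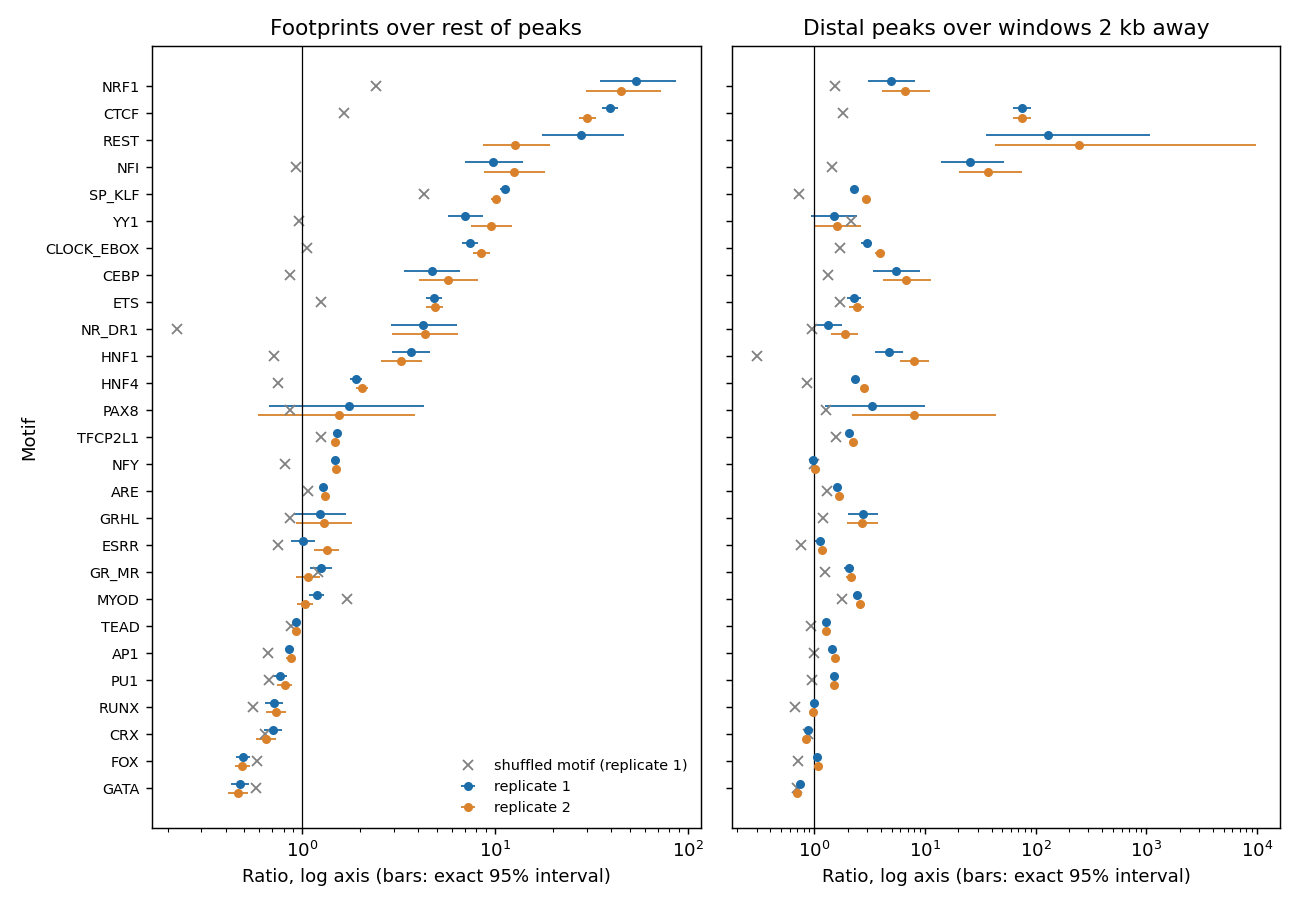
Ratio of motif density in footprints to the rest of the peaks (left) and of motif frequency at distal peaks to windows 2 kb away (right), on log axes, in replicate 1 (blue) and replicate 2 (orange) with exact 95% intervals. Crosses mark shuffled motifs in replicate 1, and CTCF stands at 39.4 and 30.2 on the left and 75.2 in each library on the right.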

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

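The tests of the Y chromosome peaks were set before their results were seen. Both libraries come from females, yet 53 peaks in replicate 1 and 38 in replicate 2 were called on chromosome Y, above the 3 that a count of 0 allows. They are sparse, at 0.601 and 0.431 per Mb against 59.3 and 54.02 on the autosomes. In each library 21 of them were nearest to Mid1-ps1, a pseudogene of Mid1, from Y:90717590 to Y:90744820 in replicate 1, where the highest reached 10.1 and, in replicate 2, 6.12. Male cells in the tissue are argued against by the promoters of Ddx3y, Eif2s3y, Kdm5d and Uty, of which 0 of 8 over both libraries held a peak, while the promoters of their X copies held peaks at least 139 times as high as the lowest peak of the library. Sequence shared with other chromosomes remains a candidate source: 71.7% and 63.2% of Y peaks had at least 50% of their 24-base words on another chromosome, against 1.30% and 1.90% of 1000 autosomal peaks (Fisher's exact test, two-sided, p = 3.6e-46 and 2.0e-27). Random intervals of chromosome Y were not drawn, so the test cannot tell these peaks from Y sequence in general. Neighbouring peaks, such as those near Mid1-ps1, are also not independent. The remaining Y peaks, with under 50% of their words on another chromosome, were not explained by this test, and nearly all of them lay near Mid1-ps1. In replicate 2 the peaks at Y:90740061-90740380 (height 2.35) and Y:90739601-90739800 (height 1.79) had 1.01% and 0% of their words on another chromosome. The highest peaks near Mid1-ps1 in replicates 1 and 2 had 83.9% and 76.1%. Peaks nearest to other genes had low median heights of 0.0675 and 0.101.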

How the results depend on the processing

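The shorter list for Y peaks, promoters without a CpG island, comparison with every shuffled motif, basic TSSs, footprints in shared peaks and some single-library values were chosen after seeing the data. Peaks per library fell to 90222 with the shorter list and 69613 at or above the joint median height. The shared share was 60.3% with reciprocal overlap, 87.8% for equal numbers of the highest peaks and 95.5% for the higher 50% of peaks. The Spearman correlation of heights across peaks was 0.951 with reciprocal overlap and 0.911 in the higher 50%. The promoter share was 21.2% at 500 bp, 36.8% at 2 kb, 34.9% with the shorter list and 39.1% in the higher 50%. Shared footprints rose to 60.1% in shared peaks of the higher 50%. Cutting below an FDR of 0.001 fell to 19.2 Mb inside peaks, and Y peaks to a mean of 25 with the shorter list, both by construction since less sequence is counted. Lists called higher numbered 5 with the shorter list, 5 with the higher 50% and 1 with the reduced background, and lists called lower 1 without CpG islands. Beyond every shuffled version, motifs called higher numbered 11 in footprints and 14 at distal peaks, and motifs called lower 1 and 0. At distal peaks ESRR turned to 0.966 in the higher 50% and FOX to 0.987 in windows of 100 bp. In each case the cause was not tested unless stated. Single libraries gave 132670 to 145393 peaks, 71.9% to 80.1% shared, a promoter share of 27.8% to 29.4%, 385715 to 472224 footprints, 43.1% to 52.8% of them shared, 29.3 to 37.9 Mb of cutting, 38 to 53 Y peaks, 1 to 2 lists low in distal peaks (neuronal genes joined in replicate 2) and 9 lists called higher. The lists high in distal peaks were joined by the thick ascending limb and principal cell lists in replicate 1, and by the podocyte and adipocyte lists in replicate 2. Calls of single lists or motifs were unchanged in most settings: 185 of the promoter list settings, 121 of the footprint motif settings and 146 of the distal motif settings. In the same order 21, 10 and 11 calls were lost without a change of direction and 1, 4 and 2 were gained, and the ESRR and FOX calls at distal peaks were lost as their direction turned. The PAX8 motif gave no finite ratio in the higher 50% of distal peaks, and the pluripotency motif gave none in any setting. The stricter share of footprints could not be run, since every footprint carries the same value. No paired analysis was possible because there is only 1 group. Depth is unknown, and peaks of the lowest decile of height were shared least, at 21.2% and 34.0%.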

Other observations

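The tests of distal peaks near tubule and Hox genes and of the highest distal peaks were chosen only after the result was seen. Chromosome X was less open than the autosomes, with 20.6 and 19.9 peaks per Mb in replicates 1 and 2 against 59.3 and 54.02, and median heights of 0.440 and 0.493 against 0.615 and 0.751. Of all protein-coding genes on X, 51.6% and 51.4% held a promoter peak, against 72.2% and 71.4% on the autosomes. With a CpG island the shares were closer, at 94.7% and 94.3% against 98.0% and 97.8%. Among genes with a promoter peak and a CpG island, X genes outside the escape group had promoter heights lower than autosomal genes by a log2 difference of -0.96 and -1.04. The median of Ddx3x, Eif2s3x, Kdm5c and Kdm6a, which are known to escape X inactivation, stood above these X genes by 1.39 and 1.63 on the log2 scale (permutation test, p = 0.00030 and 0.00048). Kdm6a stood at 14.6 and 27.3, Kdm5c at 8.83 and 17.4, and Ddx3x at 8.90 and 8.77. Eif2s3x, at 6.87 and 5.46, lay below the autosomal median of 8.21 in replicate 2. The promoter heights leave closed chromatin on the inactive copy as a hypothesis, and the cause of the lower number of peaks on X was not tested. These 4 genes are used in many tissues, and whether they would be higher without X inactivation was not tested.

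The highest distal peaks may partly reflect sequence present in several copies. Of the 20 highest, 30% had at least 50% of their words more than once in the assembly, against 2.60% of 1000 other distal peaks (Fisher's exact test, two-sided, p = 1.7e-05). The highest by the mean of the libraries, among distal peaks matched 1 to 1, lay at X:169997921-169998240 in an intron of Mid1. It reached 51.6 and 60.3 and was repeated over 100% of its words, all of them on another chromosome. The count included chromosome Y, which females lack, and a copy there alone would give this value. This peak therefore does not show several copies in these genomes, although it is among the 30%. The next, intergenic at 3:5860361-5860530, reached 53.6 and 32.2, above the former in replicate 1, and was also repeated over 100% of its words. Those in the untranslated region of Lars2, at 9:123461881-123462140, and in an intron of Il31ra, at 13:112578161-112578340, were repeated over 69.6% and 72.0%. That in the untranslated region of Cers5, at 15:99735661-99736060 with heights of 41.5 and 30.03, was not repeated.

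Distal peaks were more numerous in replicate 1 around all genes, with a median of 6 against 5, and around most tubule lists, with 11.5 against 9.5 for the proximal tubule, 10.5 against 5.5 for the thick ascending limb, 10.5 against 8.5 for principal cells, 7 against 6 for the distal convoluted tubule and 9 in each library for intercalated cells. Whether any tubule list exceeded the general difference in number was not tested. A larger share of proximal tubule and thick ascending limb cells in replicate 1 is argued against, since the matched peaks near the genes of these 2 lists were not relatively higher there: their median log2 ratios ranked at most at the 15.55th percentile of 2000 random lists. The principal cell list ranked at 6.55, but the distal convoluted tubule list at 80.6 and the intercalated cell list at 53.6, so that the argument does not extend to every tubule cell type. A looser cut-off on the FDR of the cut rate in replicate 1 is argued against. In each library 100% of main-list peaks had a lowest FDR below 0.05, and 100% of shorter-list peaks one below 0.001. Of main-list peaks, 66.49% and 67.02% in replicates 1 and 2 had a lowest FDR below 0.001. Greater depth in replicate 1, or a lower threshold on another measure, could account for the higher numbers but cannot be told apart from other causes. The lower rank of the proximal tubule and thick ascending limb lists lay at a percentile of 2. That is just below the central 95% of random lists that such depth or threshold predicts, but far from the high ranks that would exclude it. Peak GC content and height likewise stay open, with a lower rank of 5.7 for these 2 lists after centring, since their ranks were low before centring too. Hox genes, with 32 against 21 distal peaks, had matched peaks that leaned the other way, with a median log2 ratio of 0.09 against -0.16 in random lists, at the 100th percentile. Centring on GC content and height left it at 0.25 against 0.02, again at the 100th percentile, so the centring did not bring it closer to random lists. The Hox genes lie in clusters and share their 87 matched peaks, while random lists drew genes singly. The percentiles therefore cannot tell how unusual the Hox values are, and explanations of them were not tested further.

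It was asked whether motifs of known regulators were more frequent in distal peaks near the genes of their cell type than in other distal peaks. No pair passed Fisher's exact test with Benjamini-Hochberg adjustment over the 7 pairs in each library. The lower odds ratio of the libraries was 0.755 for HNF4 and 1.40 for HNF1 near proximal tubule genes, 0.762 and 1.40 for TFCP2L1 near thick ascending limb and principal cell genes, 2.33 for ETS near endothelial genes, 1.07 for AP-1 near injury and senescence genes and 1.35 for the E-box near clock genes. For HNF4 near proximal tubule genes (0.755 and 0.882) and TFCP2L1 near thick ascending limb genes (0.940 and 0.762) the odds ratio was below 1 in both libraries. That was the outcome set in advance against a role of these factors there. Few peaks near each list held a motif, such as 2 of 212 for ETS near endothelial genes in replicate 1. The intervals of all odds ratios included 1, so that these comparisons left both directions open.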
